A study of Homo sapiens with 4 samples.

How the data were processed

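ATAC-seq was done on 50000 to 100000 day 6 cardiac precursor cells per sample, with hyperactive Tn5 and paired-end reads of 42 bp on an Illumina NextSeq, per the labels' protocols. The labels list 4 libraries, 2 of high and 2 of low terminal cardiomyocyte purity, described as biological replicates; they name total RNA as the molecule, which is at odds with the assay they describe. Whether the replicates came from separate differentiation runs is not stated further, so p-values measure the spread between these libraries. Groups were taken from the sample titles.

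BWA, MACS2 and DESeq2 and the builds GRCh38 and hg38 are named per the submitters' processing notes, with no versions, settings or order. Read shifting for Tn5, duplicate removal, filters on repeats and whether peaks were called per library or on pooled libraries are not given in the sources used here. Each of these choices could change a peak's count, above all in sequence present in many copies. The deposited table holds, per the file headers, the authors' mean normalized count of each peak (a signal averaged over all libraries), the log2 fold change and its standard error, the Wald score, and the p-value with its adjusted value. It also holds an Up, Down or unmarked label and, for some peaks, a gene symbol. The authors' score equalled the log2 fold change divided by its standard error to within 1.7e-07. Whether the fold changes were shrunken is not given in the sources used here. The authors' deposited p-value equalled the two-sided normal p of the score to within 5.0e-08, and the adjusted p-value its Benjamini-Hochberg adjustment over all 60875 peaks to within 3.4e-06. The authors' marking equalled an absolute log2 fold change of at least 1 with an unadjusted p under 0.05 in every peak (0 exceptions). Values per library were not analysed here, so depth, replicate scatter and any batch could not be examined.

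The design fixed before the data were examined was a test on counts per library. Because the values were of another unit, its branch for a table of the authors' comparison was used, with the authors' adjusted p under 0.05 and no test per peak of this work's own. Coordinates are given as the authors' deposited table gives them, on GRCh38 per the submitters' processing notes; whether starts count from 0 or 1 is not stated. Exons, introns and strand are not given in the sources used here. Gene bodies came from RefSeq (GCF_000001405.40, GRCh38.p14): of 11788 symbols in the table, carried by 13103 peaks, 95.3% were found there, and 12464 peaks lay on the chromosome of their gene.

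Peaks were named by a rule fixed before the data were examined. It took the 10 largest absolute fold changes per side among peaks with an adjusted p under 0.05, a symbol and a mean count at or above the median, 1 per gene. It also took up to 3 genes per list with the smallest p, where the list or the gene's peak passed, and the best peak of 14 marker genes. This gave 36 peaks, of which 31 passed; a few of them are not reported here. In all, 22 gene lists of lineages, pathways and other cell types were fixed at the same time. Per side, the share of list genes with a changed symbol-bearing peak was compared with all other symbol-bearing genes (Fisher's exact test, two-sided, Benjamini-Hochberg over 44 tests), and the list's median fold change was placed among 10000 random peak lists matched on deciles of the mean count. Annotation class was the share of symbol-bearing peaks (Fisher's exact test, 95% intervals of the odds ratio from its log standard error).

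Several alternatives were chosen after the data were seen. Peaks were assigned to the nearest protein-coding gene within 100 kb, tested against 10000 random gene lists matched on peak number (permutation, two-sided). Fold changes were recentred on their running median over 2001 peaks ordered by mean count. Other alternatives were leaving out peaks within 2 Mb of the largest gene-free interval of each chromosome, keeping peaks at or above the median mean count, the authors' marking as the threshold, distance to either gene end in place of the symbol, and the Mantel-Haenszel odds ratio over deciles of mean count. Peaks near gene-free intervals were compared with 1000 draws of peaks elsewhere at neighbouring ranks of mean count, together and with chromosomes 10 and 17 apart. A pair of further lists, of liver and gut epithelium and of epithelial junctions and keratins, were written after the endoderm pattern and before their own values were seen.

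The procedures were tested on simulated fold changes drawn for the 60875 peaks of this comparison from their deposited standard errors. Of 100 peaks changed by 1 log2 unit 15% were called, of 100 changed by 2 log2 units 73%, and 4 unchanged peaks were called. Of 200 list tests with no planted change 2.5% gave a Fisher p under 0.05 over 11788 genes. The simulation drew peaks independently and held far fewer changed peaks than the deposited comparison. Its shares therefore do not give the power or the error rate of the tests on the deposited values. The nearest-gene test was also run on random gene lists with the deposited calls. There 0% of 200 tests gave a permutation p under 0.05, so that test may be too strict. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.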

Results

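Chromatin accessibility was mapped by ATAC-seq, in which the transposase Tn5 inserts sequencing adapters into open chromatin, in cardiac progenitor cells on day 6 of differentiation. The cells came from WTC11, an established human induced pluripotent stem cell line. Of the 4 libraries, 2 came from differentiations that went on to a high purity of cardiomyocytes and 2 from differentiations that ended in low purity. The comparison asks which accessible regions of the progenitors differ between these outcomes. The values analysed here are the authors' DESeq2 comparison of 60875 peaks, with no value per library. The depth of each library is therefore unknown, and the spread between replicates enters only through the standard error (SE) of each fold change. Mean normalized counts per peak ran from 9.27 to 10265 with a median of 47.8, and the median SE was 0.39 log2 units. Peaks that the authors' deposited table marks Up have negative log2 fold changes and those it marks Down have positive ones. Which group is the numerator is not given in the sources used here. Differences are therefore named by the Up side (negative) and the Down side (positive) and are assigned to neither purity group.

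Symbol-bearing peaks of 4 of 17 contractile apparatus genes changed on the Up side. That of the cardiac transcription factor gene NKX2-5 did so narrowly, as the only changed gene of 8 in its list. Symbol-bearing peaks of the endothelial genes TEK and NOS3 changed on the Down side. The peak of MYH7, which encodes the beta myosin heavy chain, had a log2 fold change of -1.81 ± 0.35 (SE) in the authors' deposited table (adjusted p = 4.76e-05; chromosome 14, 23438101 to 23438573, 2441 bp from the gene). For TEK, the angiopoietin receptor gene, the authors' deposited table gives 1.19 ± 0.32 (SE, adjusted p = 0.00692; chromosome 9, 27108951 to 27109527, overlapping the gene). In all, 3655 of 60875 peaks (6.0%) had an adjusted p under 0.05 in the authors' deposited table. Of these, 1437 lay on the Up side and 2218 on the Down side. The median change was -1.41 log2 units on the Up side, a 2.65-fold difference, and 1.48 on the Down side, a 2.80-fold difference. An adjusted p under 0.01 left 643 peaks on the Up side and 1249 on the Down side. The authors' own marking follows an absolute log2 fold change of at least 1 and an unadjusted p under 0.05. It takes in 2959 Up and 3034 Down peaks, of which 41.2% and 66.0% had an adjusted p under 0.05.

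**Figure D1:**
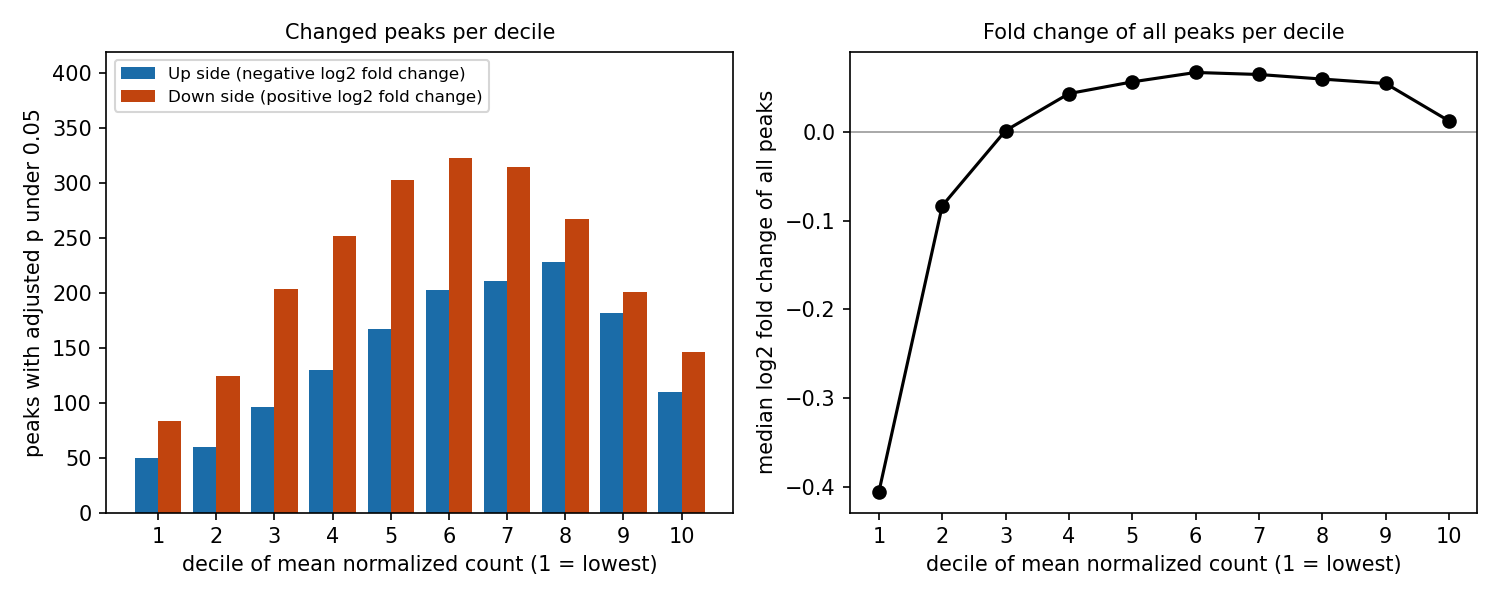
Left, peaks with an adjusted p under 0.05 on the Up side and on the Down side, in each decile of the mean normalized count (x axis, 1 is the lowest), from the authors' deposited table. Right, the median log2 fold change of all peaks in the same deciles, which is -0.41 in the lowest decile and between -0.08 and 0.07 in the others.

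Peaks carrying a gene symbol were less frequent among changed peaks than among peaks that did not pass. On the Up side 164 of 1437 peaks (11.4%) carried a symbol, against 22.4% of the 57220 peaks that did not pass (odds ratio 0.446, 95% interval 0.379 to 0.525, Fisher's exact test, two-sided, p = 2.0e-26). On the Down side the share was 112 of 2218 (5.05%), with an odds ratio of 0.184 (0.152 to 0.223, Fisher's exact test, p = 5.5e-111). Of the symbol-bearing peaks that matched a RefSeq gene on their chromosome, 75.2% lay within 1000 bp of an end of that gene. Bodies of protein-coding genes overlapped 51.4% of Up side and 44.9% of Down side peaks, against 59.7% of the peaks that did not pass. Peaks near one another are not independent, so the odds ratios carry more weight than these p-values.

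Of the cardiomyocyte contractile apparatus list, 4 of 17 genes with a symbol-bearing peak changed on the Up side, namely MYH7, MYL7, UNC45B and TTN. None changed on the Down side. Among the other symbol-bearing genes 1.35% had a peak on the Up side (Fisher's exact test, two-sided, adjusted p = 0.00321 over 44 list tests). MYL7, the atrial regulatory myosin light chain, had a log2 fold change of -1.15 ± 0.26 (SE) in the authors' deposited table (adjusted p = 7.3e-04; chromosome 7, 44141194 to 44141706, overlapping the gene). UNC45B, a chaperone of striated muscle myosin, stood at -1.28 ± 0.34 (SE, adjusted p = 0.00761) in the authors' deposited table. The TTN peak, named after its value was seen since it is the remaining gene of the 4, stood at -1.37 ± 0.41 (SE, adjusted p = 0.0202) in the authors' deposited table. By RefSeq coordinates it overlaps the neighbouring gene CCDC141. Also named after their values were seen, peaks whose nearest gene is TTN (1.96 ± 0.42, overlapping the gene) and TPM1 (1.29 ± 0.43, SE) changed on the Down side in the authors' deposited table. The median log2 fold change of the 22 symbol-bearing peaks of the list was -0.50, below all 10000 random peak lists matched on mean count (95% range -0.13 to 0.21). Adjusted over the list alone, 7 peaks passed on the Up side and 1 on the Down side. Taking every peak within 100 kb of its nearest protein-coding gene, 6 of 20 genes changed on the Up side, where random gene lists gave 1.71, and the median of all 82 peaks was -0.099. That test did not pass (permutation, adjusted p = 0.155), but it did at an adjusted p under 0.01 per peak (5 genes, permutation, adjusted p = 0.0352). Peaks near endoderm genes lay on the same side, in 10 of 16 genes of that list.

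The endothelial and haematoendothelial list had 2 of 6 genes with a symbol-bearing peak on the Down side, against 0.934% of other genes (Fisher's exact test, adjusted p = 0.0288). Beside TEK, NOS3, the endothelial nitric oxide synthase gene, stood at 1.10 ± 0.33 (SE, adjusted p = 0.0221) in the authors' deposited table. The GATA2 peak had -0.65 ± 0.40 (SE, adjusted p = 0.448) in the authors' deposited table. The median of the 7 symbol-bearing peaks of the list was 0.34, at percentile 97.9 of matched random lists. Adjusted over the list alone, 2 peaks passed on the Down side. The call ended at an adjusted p under 0.01 per peak (1 gene, Fisher's exact test, adjusted p = 0.297). With nearest genes, 5 of 17 genes changed on the Down side against 2.73 in random lists (permutation, adjusted p = 1). On the Up side 3 genes changed (CDH5, FLT1 and RUNX1, named after their values were seen), against 2.11 in random lists, and the median of all 91 peaks was 0.015.

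Peaks around endoderm genes changed on the Up side once peaks were given to their nearest protein-coding gene, an assignment chosen after the data were seen. Of the 16 endoderm list genes with a peak within 100 kb, 10 had a peak on the Up side, where random gene lists matched on peak number gave 1.82. The adjusted p was 0.0088 (permutation), the smallest these random lists can give over 44 tests. On the Down side 3 genes had a changed peak. The 76 peaks of the list held 18 on the Up side and 4 on the Down side, or 24 and 5 adjusted over the list alone, with a median log2 fold change of -0.62. FOXA2, a pioneer transcription factor of endoderm, had 7 of 11 peaks on the Up side. The peak overlapping FOXA2 (chromosome 20, 22584207 to 22585003) stood at -1.003 ± 0.29 (SE, adjusted p = 0.0169) in the authors' deposited table. A peak 89689 bp away stood at -1.97 ± 0.39 (SE, adjusted p = 6.39e-05) in the authors' deposited table. HNF4A, a nuclear receptor of the liver and gut, had a peak overlapping its gene body at -1.14 ± 0.28 (SE, adjusted p = 0.00247) in the authors' deposited table. Peaks near SOX17 (-1.77 ± 0.55, SE), HHEX (-1.21 ± 0.38, SE) and EPCAM (-0.95 ± 0.26, SE) also changed on the Up side in the authors' deposited table. APOB had 1 peak on the Up side and 2 on the Down side. By symbol alone, 1 of 6 endoderm genes had a changed peak, APOA1 at -0.81 ± 0.27 (SE, adjusted p = 0.0491) in the authors' deposited table. The list did not pass by symbol (Fisher's exact test, adjusted p = 0.504). Its 8 symbol-bearing peaks had a median of -0.46 (percentile 1.32), and 2 passed on the Up side adjusted over the list alone.

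**Figure D2:**
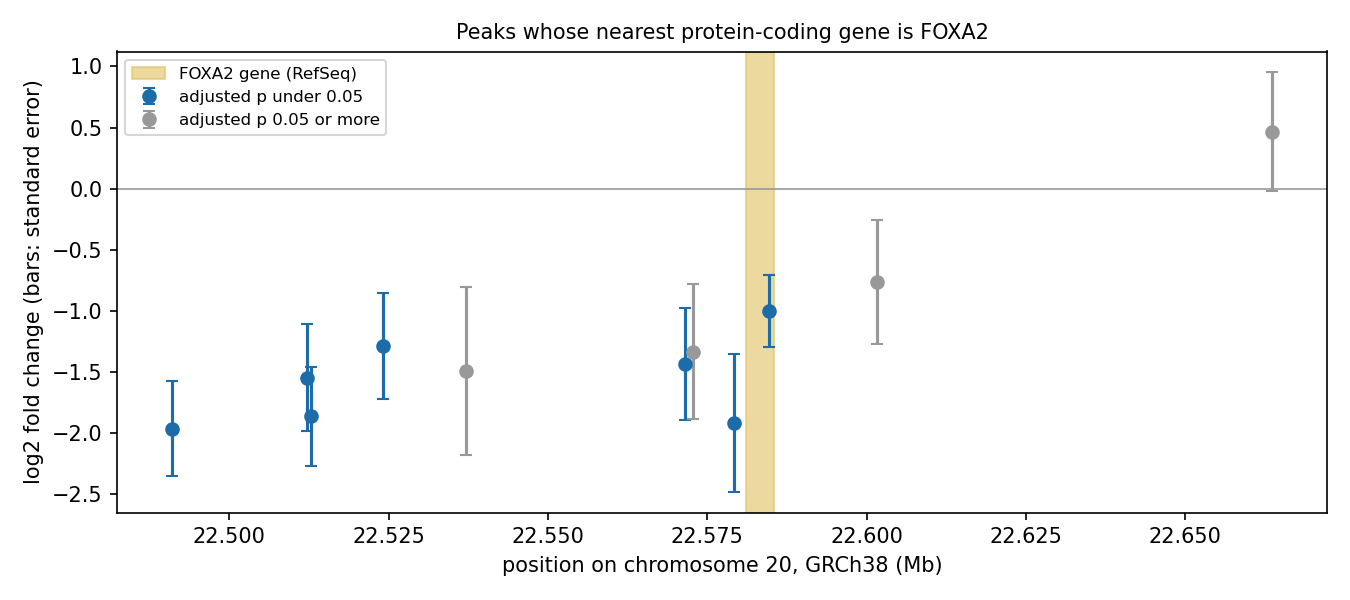
Log2 fold change (y axis) with its standard error (bars) of the 11 peaks whose nearest protein-coding gene is FOXA2, by position on chromosome 20 in Mb (x axis), from the authors' deposited table; negative values are the Up side. The 7 peaks with an adjusted p under 0.05 lie between -1.97 and -1.003, and the shaded bar is the RefSeq gene.

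At an adjusted p under 0.05 per peak the remaining lists did not pass by symbol or by nearest gene. Among the cardiac progenitor transcription factors 1 of 8 genes with a symbol-bearing peak changed, NKX2-5 on the Up side at -0.92 ± 0.31 (SE, adjusted p = 0.0474) in the authors' deposited table. The median of that list's 8 symbol-bearing peaks was 0.15, at percentile 86.8 of random lists matched on mean count. The peak labelled FGF8, a fibroblast growth factor gene, stood at -0.76 ± 0.21 (SE, adjusted p = 0.0109) in the authors' deposited table. By RefSeq coordinates that peak overlaps NPM3, in part or in whole. FGF8 was the only changed gene by symbol among 4 of primitive streak and early mesoderm and among 10 of cardiac progenitor signalling and surface. Among 11 BMP and NODAL pathway genes only the BMP inhibitor SMAD6 changed by symbol, at -1.15 ± 0.27 (SE, adjusted p = 0.00165) in the authors' deposited table. Adjusted over that list alone, 3 peaks passed on the Up side and 1 on the Down side. The list passed at an adjusted p under 0.1 per peak (3 of 11 genes on the Up side, Fisher's exact test, adjusted p = 0.0246). The retinoic acid pathway list, with 7 genes by symbol, did not pass (Fisher's exact test, adjusted p = 0.504 on the Down side). With nearest genes, 3 of 5 genes of HOX paralogue groups 1 to 5 had a Down side peak, against 0.367 in random lists, which did not pass (permutation, adjusted p = 0.088). THY1, a surface glycoprotein of fibroblasts among other cells, stood at 1.36 ± 0.33 (SE, adjusted p = 0.00189) in the authors' deposited table. The WNT effector LEF1 stood at 0.67 ± 0.22 (SE, adjusted p = 0.0443) and the basement membrane collagen gene COL4A2 at 1.297 ± 0.40 (SE, adjusted p = 0.0253) in the authors' deposited table. By RefSeq coordinates the peak labelled COL4A2 overlaps COL4A1. A peak overlapping COL4A2, named after its value was seen, changed on the Up side, at -1.43 ± 0.30 (SE, adjusted p = 0.000199) in the authors' deposited table. THY1, LEF1 and COL4A2 were the only changed genes by symbol among, in turn, 12 of smooth muscle and fibroblast, 8 of the WNT pathway and 18 of extracellular matrix and adhesion. Adjusted over the list alone, 1 peak passed on the Up side in each of the primitive streak, cardiac progenitor transcription factor and cardiac progenitor signalling lists, and 1 on the Down side in the first 2 of these. On the Down side 1 peak each passed in the same way in the smooth muscle and fibroblast, WNT and matrix lists. The median of the 13 symbol-bearing smooth muscle and fibroblast peaks was 0.37, at percentile 99.97 of random lists matched on mean count. Over all 79 peaks near genes of that list it was 0.049, with 3 peaks on the Up side and 5 on the Down side.

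No gene changed by symbol in the other 10 lists. These held 8 genes of pluripotency with a symbol-bearing peak, 9 of calcium handling, ion channels and peptides, 9 of neural ectoderm and 3 of neural crest. They also held 5 of paraxial mesoderm and somite, 4 of intermediate mesoderm and kidney, 5 of the epicardium, 5 of HOX paralogue groups 6 to 13, 10 of AP-1 and stress response and 10 housekeeping genes. Adjusted over the list alone, 1 pluripotency peak passed, on the Up side. With nearest genes, the adjusted p of the list tests other than those of the endoderm, contractile and HOX 1 to 5 lists was 0.968 or more (permutation).

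**Figure D3:**
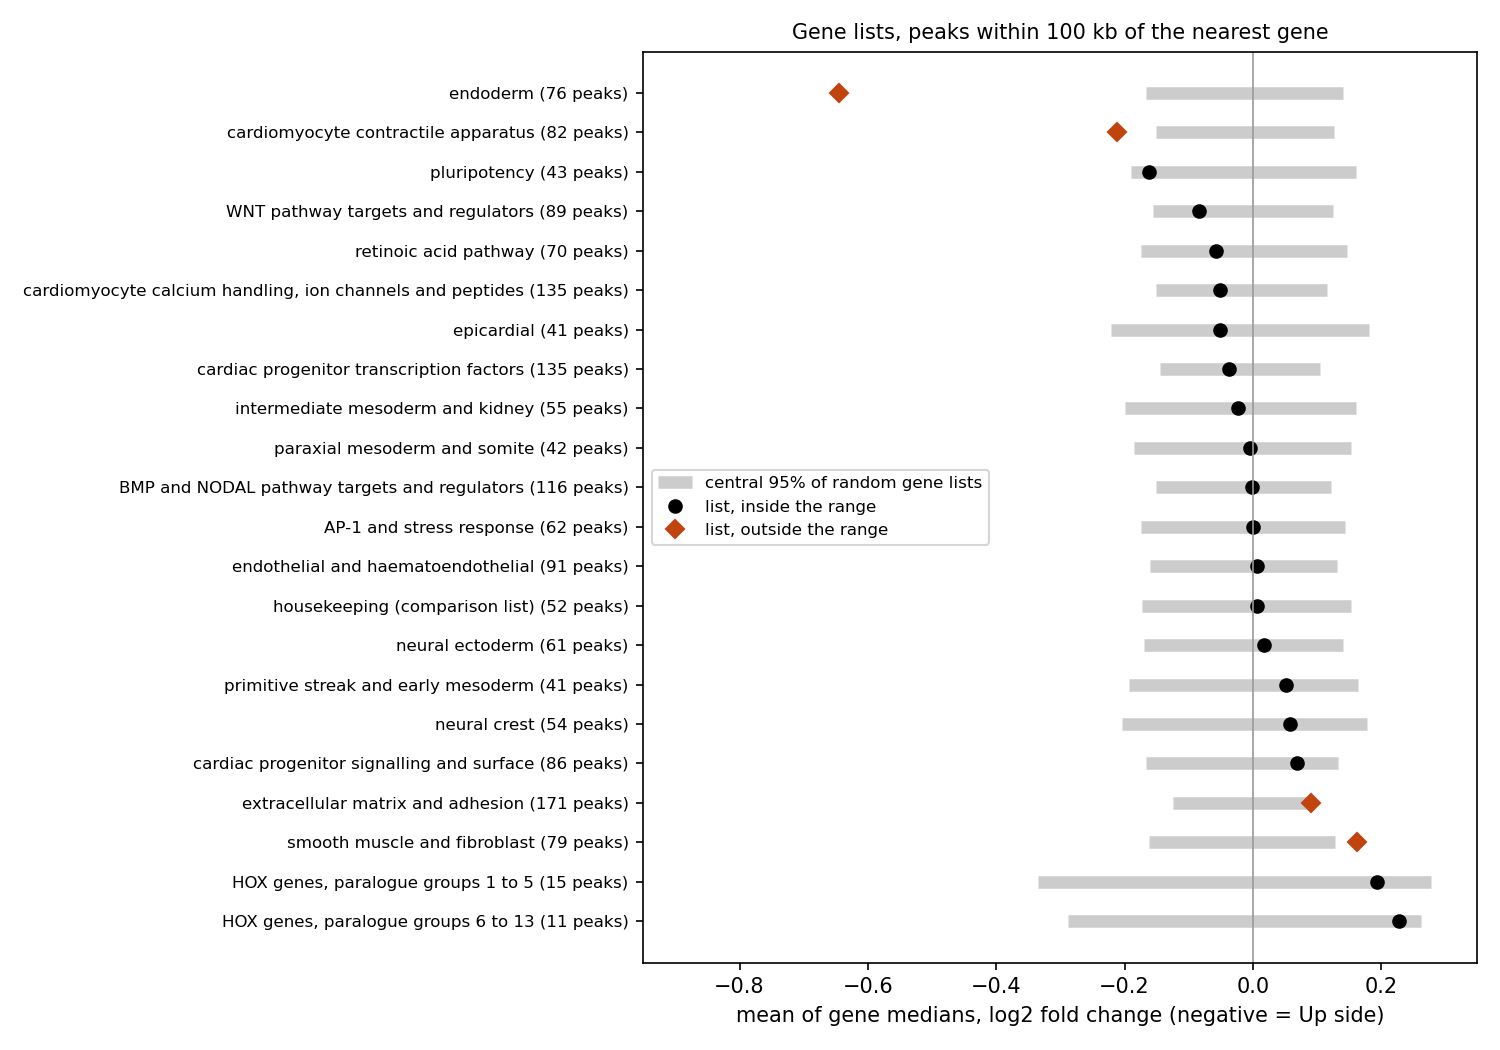
Mean over a list's genes of each gene's median log2 fold change (x axis) for 22 gene lists, with peaks within 100 kb given to their nearest protein-coding gene; grey bars are the central 95% of 10000 random gene lists matched on peak number. Means of 4 lists lie outside their range, the endoderm list at -0.65 and the contractile list at -0.21 on the Up side, and the smooth muscle and fibroblast list at 0.16 and the matrix and adhesion list at 0.09 on the Down side; in 8 lists the mean and the median over peaks differ in sign.

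The largest changes on the Up side among symbol-bearing peaks at or above the median mean count were at long noncoding RNA genes, a sodium channel gene and a pseudogene. In the authors' deposited table the peak of LINC01944 stood at -2.16 ± 0.35 (SE, 4.47-fold, adjusted p = 4.39e-07), that of SCN7A at -2.15 ± 0.39 and that of CDC42P3 at -2.09 ± 0.41. MYH7 and NR0B2, an orphan nuclear receptor active in bile acid metabolism, were also among these 10 peaks. NR0B2 stood at -1.76 ± 0.36 (SE, adjusted p = 1.7e-04) in the authors' deposited table. The others, RTL8C, LINC01843, MIR5694, LOC100134368 and C10orf95, ran from -1.82 to -1.69 in the authors' deposited table. Symbols are the authors' labels. The SCN7A peak lay 120242 bp from the RefSeq gene. The peaks labelled NR0B2, MIR5694, LOC100134368 and TM6SF2 overlapped NUDC, GPHN, PGAP6 and SUGP1, in that order. Among symbol-bearing peaks at or above the median mean count, the largest change on the Down side was at MIR4725. It stood at 2.93 ± 0.33 (SE, 7.65-fold, adjusted p = 2.42e-14, chromosome 17, 31571095 to 31571924) in the authors' deposited table. TM6SF2, a gene of lipid metabolism, stood at 2.21 ± 0.38 and SPATS2L at 2.14 ± 0.40 (SE) in the authors' deposited table. The carnitine transporter gene SLC22A5 stood at 1.94 ± 0.34 and PTK2, the focal adhesion kinase gene, at 1.91 ± 0.38 (SE) in the authors' deposited table. The peak labelled MIR1245A overlapped COL3A1, a fibrillar collagen gene, and stood at 1.84 ± 0.36 (SE, adjusted p = 6.19e-05) in the authors' deposited table. HPCAL1, EPN2-IT1 and CIDEC ran from 1.73 to 1.70 in the authors' deposited table.

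Of 14 cell type marker genes chosen in advance, 5 had a symbol-bearing peak, and only that of NKX2-5 passed. HAND1, a transcription factor of the heart field, stood at 0.58 ± 0.22 (SE, adjusted p = 0.0987) in the authors' deposited table. The other values were, for MYH6, the alpha myosin heavy chain gene, -1.06 ± 0.45 (SE, adjusted p = 0.161), for TNNT2, the cardiac troponin T gene, -0.35 ± 0.41 (SE, adjusted p = 0.806) and for the symbol-bearing peak of SOX17 -0.23 ± 0.49 (SE, adjusted p = 0.914) in the authors' deposited table. The peak labelled TNNT2 overlaps LAD1 by RefSeq coordinates.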

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

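The authors' marking, the minimum mean count, the nearest genes, recentring, the distance to a gene end, leaving out peaks near gene-free intervals and the Mantel-Haenszel odds ratio were chosen after the data were seen. No paired analysis was possible because no value per library was analysed. For the same reason the planned TMM, DESeq2, library total and loess scalings, count filters, pseudocounts, the DESeq2 rerun, leaving out each library, camera and fry were not run. The promoter windows were not run because gene strand was not given. At an adjusted p under 0.01 the 3655 changed peaks became 1892 (643 Up, 1249 Down) and 1 list test passed in place of 2; at under 0.1 the Up side had 2193, and 3 list tests passed, adding the BMP and NODAL list on the Up side (3 of 11 genes, Fisher's exact test, adjusted p = 0.0246). Fewer or more peaks follow from these 2 thresholds by construction. The authors' marking, another rule, gave 5993 peaks (2959 Up). It kept 1218 of the 1437 Up side peaks and 2003 of the 2218 Down side peaks. The 30438 peaks at or above the median mean count, with p adjusted again over these alone, gave 2340 (1004 Up, 1336 Down). Of these, 934 and 1252 had also changed over all peaks. With nearest genes 1 list test passed, that of the endoderm list, and at an adjusted p under 0.01 per peak 2 passed, adding the contractile list (5 genes, permutation, adjusted p = 0.0352, against 0.155 before); the cause was not tested. Recentring by mean count gave 1611 Up and 2073 Down, with 1376 and 2005 of the same peaks, and the same 3 list tests passed (BMP and NODAL list, 3 genes, adjusted p = 0.0120, same test). The odds ratio for symbol-bearing peaks stayed below 1 in every alternative run, at 0.243 to 0.482 on the Up side and 0.109 to 0.204 on the Down side. None of the 36 named peaks changed sign on recentring; LEF1 no longer passed (0.65 after, 0.67 ± 0.22 before), its recentred value being smaller. The same holds for the changed peaks printed for GATA6 (0.81 after, 0.89 ± 0.30 before) and TPM1 (1.22 after, 1.29 ± 0.43 before, SE, in the authors' deposited table), named by no rule. At an adjusted p under 0.01, 6 named peaks no longer passed (FGF8, NKX2-5, NOS3, APOA1, LEF1, COL4A2), and a minimum of 1 log2 unit left out 4 of these. Simulated changes of 1 log2 unit were called in 15% of peaks. The simulation held far fewer changed peaks than the deposited comparison, so this share cannot show which differences the deposited values miss. In the deposited comparison, 434 peaks with an absolute change under 1 log2 unit had an adjusted p under 0.05.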

Other observations

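The genes of the next paragraph, the counts of changed peaks per gene, and the tests on gene-free intervals, together and with chromosomes 10 and 17 apart, the highest mean counts, chromosome 21 and the pooled other cell types were chosen only after the result was seen, while the liver and epithelial lists and the recentring were added after the endoderm pattern and before their own values were seen.

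Single changed peaks near cardiac transcription factor genes lay on both sides. The cardiac progenitor transcription factor list had 19 genes with a peak within 100 kb. Of these, 5 had a changed peak on the Up side and 2 on the Down side. Random gene lists gave 3.14 and 4.11, and neither side passed its permutation test. In the authors' deposited table a peak near TBX20 stood at -2.10 ± 0.60 (SE), one near GATA4 at -1.61 ± 0.42 and one near TBX3 at -1.71 ± 0.53. A peak near TBX5 stood at 2.22 ± 0.46 and one overlapping GATA6 at 0.89 ± 0.30 (SE) in the authors' deposited table. The GATA6 peak no longer passed after recentring by mean count. MYOCD, a coactivator of smooth and cardiac muscle genes, had a peak overlapping the gene at -1.59 ± 0.22 (SE, adjusted p = 1.52e-09) in the authors' deposited table. All 3 changed peaks near WT1, an epicardial and kidney transcription factor gene, lay on the Down side, from 1.99 to 2.98, as did 4 near ETS1, from 0.83 to 2.40, in the authors' deposited table. Of 3569 genes with 5 or more peaks away from the gene-free intervals, 3 were picked out by a hypergeometric test that takes peaks as independent draws. They were FOXA2 with 7 of 11 peaks on the Up side, SMAD6 with 6 of 17 on the Up side and DEFB115 with 6 of 6 on the Down side. Neighbouring peaks are not independent, so no p-value is given for these counts. The SMAD6 peaks on the Up side ran from -1.28 to -0.90 in the authors' deposited table, and the DEFB115 peaks, at 31157086 to 31187418 on chromosome 20, lay over 70 kb from that gene. The largest gene-free interval of chromosome 20 ends at 28580632, so the DEFB115 peaks lay past its 2 Mb flank but close to it. Their mean counts ran from 96.1 to 809, against a median of 47.8 over all peaks. Whether they share a cause with the peaks beside that interval was not tested. Among the 50 peaks with the highest mean counts, the 39 without a symbol had a median of 1.02 (21 on the Down side) and the 11 with one -0.18 (none changed), and the 67 peaks below 11 Mb on chromosome 21 had 0.86 (22 on the Down side).

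The endoderm list's peaks lay on the Up side, with a median of -0.62. The tables argue against a trend of fold changes with mean count as the whole cause, since the median after recentring was -0.58. A lower share of the main cell type through a joint rise of other cell types would move their markers too. The 406 pooled peaks of 7 other cell type lists had a median of 0.024 (10 Up, 20 Down), which argues against such a joint rise. A lower share through cells of 1 kind alone would leave these lists unmoved, so these peaks cannot decide on it. Fewer cells of the main type would move their markers to the Down side. The contractile list's 22 symbol-bearing peaks instead had a median of -0.50 (random range -0.13 to 0.21). With nearest genes, 7 of its peaks changed on the Up side and 2 on the Down side. For that list the values argue against fewer such cells. The 8 symbol-bearing peaks of cardiac progenitor transcription factors, at 0.15, lay inside their range (-0.15 to 0.23) and cannot decide. More cells of a liver, gut or epithelial kind in one group may account for the endoderm pattern and stays open. The epithelial list had a median of -0.41, below all 10000 random lists. Of its 24 genes, 7 changed on the Up side, against 1.86 in random lists (permutation, adjusted p = 0.0064). That adjustment ran over both sides of the epithelial and the liver and gut list only. The liver and gut list had a median of -0.12 (percentile 3.93), inside the range of random lists (-0.13 to 0.13). Of its 18 genes, 1 changed, on the Up side, against 1.07 in random lists. Its mean over genes, -0.35, lay below the range of random lists (-0.17 to 0.14). A difference within the progenitors themselves between the purity groups was not tested and stays open, as does which group the Up side stands for.

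Peaks within 2 Mb of the largest gene-free interval of each chromosome were on the Down side in 9.15% of 1060 cases, against 4.34% (95% range 3.21 to 5.57) of peaks elsewhere at neighbouring ranks of mean count, and on the Up side in 2.17%. The draws took single peaks across the genome, whereas these peaks lie in clusters and are not independent. All ranges from the draws are therefore likely too narrow. On chromosomes 10 and 17, set apart because they held the most Down side peaks, that is, chosen on the outcome, the tables argue against a trend with mean count: 51 of 216 peaks were on the Down side, 6.38 times the matched share, and the same choice made in each of 1000 draws gave 8 to 17 (95% range). On the other chromosomes a trend cannot be told apart from other causes, since 46 of 844 peaks (5.45%, 1.21 times the matched share) lay inside the matched range (3.32 to 5.92) but above the 24 to 44 peaks that the same choice gave. Reads of sequence present in many copies could add to it, but this cannot be told apart from other causes: 16 of 21 chromosomes with 5 or more such peaks (76.2%) had a positive median, and values per library were not analysed. No biological explanation was tested.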
